A study of Mus musculus with 36 samples.

How the data were processed

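ATAC-seq libraries were made from autopod chondrocytes of FVB/NJ mouse embryos at embryonic day 15.5, per the labels. Each library pooled tissue of 3 to 5 embryos of 1 litter (6 to 10 limbs), with a target of at least 40 M reads over up to 2 sequencing rounds, per the labels' protocols. The 36 libraries form 12 groups of 3, defined by limb, element and digit. The submitters' processing notes name Bowtie2 2.3.4.1, Picard 2.9.0, MACS3 and the mm10 build, without giving a role or setting for each. How reads were trimmed, filtered or shifted is not given in the sources used here. A missing or different shift of cut sites would move peak edges by a few bases, which is small beside peaks of 1739 to 2223 bp.

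The files analysed here are 12 peak lists, 1 per group, whose peak names say that they were called on pooled libraries, and whose names state an irreproducible discovery rate selection. The authors deposited for each peak a score, a fold enrichment (a linear ratio), a −log10 p-value and a summit offset. These are the peak caller's own values and were used only to rank or leave out peaks within a list. The lowest −log10 p-value kept ranged from 23.0 to 49.6 across the deposited lists, so the lists did not end at a common significance. It was higher in digit I lists (42.65 ± 8.56, SD, n = 4 lists) than in the others (31.8 ± 4.89, n = 8, exact permutation p = 0.037) and lower in digit V lists (27.9 ± 3.83 against 39.17 ± 6.74, exact permutation p = 0.0247). A region missing from a list may have fallen below that list's threshold and need not be closed. No counts per library were analysed here, so the depth per library is unknown and replicates could not be compared. The 12 lists are the units of every exact permutation test, and the p-values of those tests measure the spread between lists. Fisher's exact tests of shares at gene ends take regions as units, and the test of over-representation draws genes. The p-values from regions or genes do not measure the spread between lists.

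Peaks of all lists that shared at least 1 bp were merged into regions, and a region was called in a list when at least 1 bp of it was covered by a peak of that list. A region separated a class when it was called in every list of the class and in no other list. Labels were swapped within strata of the other 2 factors, which gives 32 splits for limb and for element, 81 for 1 digit against the others and 216 labellings for the similarity by digit. In counts of separating regions for limb and element, each other split entered with the larger count of its 2 directions. The real split entered with the named direction, which is a strict ranking for the class with the smaller count. Jaccard indices were compared with one-sided exact permutation tests and differences of means with two-sided ones. The smallest two-sided p is 0.0312 for limb and element and 0.0123 for a digit.

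Gene positions came from a RefSeq table for GRCm38.p6, which has the same coordinates as mm10. Regions called in all lists lay within 1 kb of a gene end in 39.1% of cases, and in 5.5% and 4.3% after a shift by 100 and 1000 kb. The table has no strand, exons or sequence. Regions were therefore assigned to the protein-coding gene with the nearest end, up to 1 Mb away, where transcription start sites had been planned. Distances are from the centre of a region to that gene end. Promoters were replaced by positions within 1 kb of a gene end, and exonic and intronic positions are not told apart. The planned motif test was not run. Of the regions, 65362 were assigned to 16341 genes. The 14 gene lists held 199 genes and were fixed before the data were examined, as were the groups, the tests and the alternatives listed at the end of the next paragraph. Markers of tendon, muscle, endothelium, blood, epidermis and nerve were among them. Over-representation of a list near separating regions was tested one-sided against 10000 random lists drawn from the 50 genes nearest in number of regions, with Benjamini-Hochberg adjustment over 98 pairs of list and set. Shares at gene ends were tested with Fisher's exact test, two-sided and adjusted over 7 sets. Wilson intervals cover counting error only.

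Named genes followed a fixed rule: up to 4 members of each gene list with separating regions, the 6 genes outside the lists with the most separating regions per class (ties in alphabetical order), and 11 landmark genes (Pitx1, Tbx4, Tbx5, Hoxc10, Hoxc11, Hoxd13, Hoxa13, Sox9, Col2a1, Col10a1 and Gdf5). Other list genes were named where the number of called regions per list passed the exact permutation test at 0.05 or as examples of those that did not. The number of called regions per list gene and the share of called regions per gene list were added after the data were seen. The alternatives were peaks that cover 50% of a region, the more significant 50% of each list, lists of equal length (36194 peaks), 500-bp windows round summits, autosomes alone, a 1 kb margin of absence, a rule relaxed by 1 list, Jaccard indices over base pairs, gene assignment within 100 kb or by gene body and 10 kb, gene ends within 2 kb, and leaving out each list.

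The steps were tested on simulated calls for 65543 regions. With 200 separating regions planted per class and 5% of their calls made wrong, 101 to 115 were recovered per class and the planted class was the largest of all splits in 7 of 7 classes. This recovery follows from the settings. The planted sets were larger than any set found here (78 regions at most), so the simulation checks the steps and says nothing about finding smaller sets. Without planted regions the highest count of a class was 25, in calls drawn with the list lengths kept, once per class and independently between lists. The gene list test gave p under 0.05 in 2.5% of lists without an effect, and the share test in 3.9% of 700. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.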

Results

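Open chromatin was profiled by ATAC-seq, in which a transposase cuts accessible DNA and the cut fragments are sequenced, in E15.5 chondrocytes of the developing mouse autopod (hand and foot). The 36 libraries came from FVB/NJ embryos and formed 12 groups of 3. Each group was defined by limb (forelimb or hindlimb), skeletal element (metapodials, which are the metacarpals and metatarsals, or phalanges) and digit (I, III or V). The title of the series places these comparisons in the setting of the evolution of the human hand and foot skeleton. The files analysed here held 1 peak list per group, made from the pooled libraries, so each of the 12 lists was a single measurement with no error of its own, and the spread was taken between lists. The lists held between 36194 peaks (metacarpal digit I) and 53276 peaks (metacarpal digit III), with median peak widths of 1739 to 2223 bp. The read depth per library was unknown. Digit III lists were longer, at 47308 ± 4236 peaks (SD, n = 4 lists) against 39065 ± 3316 in the other lists (n = 8; two-sided exact permutation p = 0.0247). List length did not differ detectably between elements (exact permutation p = 0.562) or between limbs, where the exact p was higher still.

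The 12 skeletal elements shared a large part of their open chromatin. Merging the lists gave 65543 regions on mm10, of which 23353 (35.6%) were called in all 12 lists and 11127 (17.0%) in a single list. Of the regions in all lists, 39.1% lay within 1 kb of an end of a protein-coding gene, against 2.9% of the regions in 1 list. Regions shared by all lists were found near genes of cartilage. Sox9, the transcription factor that specifies chondrocytes, had 31 assigned regions, 4 of them in every list, and Col2a1, which encodes the main cartilage collagen, had 3, of which 1 was in every list. Gdf5, a growth factor of the joint interzone, had 2 regions, 1 in every list. Col10a1, a collagen of hypertrophic chondrocytes, had 3 regions and none in every list. Hoxa13, required for autopod formation, had 3 regions and 1 in every list. No region was assigned to Hoxd13 by distance, but 1 region overlapped the gene or its 10 kb flanks and was called in all lists. The 19 genes listed for resting and proliferating chondrocytes had 265 regions together, 63 of them (23.8%) in every list, and the 15 genes of prehypertrophic and hypertrophic chondrocytes had 108 regions with 29 (26.9%) in every list. Both shares were below the 35.6% over all regions. Genes of other cell types carried shared regions as well. Called in every list were 28 of 81 regions (34.6%) of the endothelial list, 7 of 34 (20.6%) of the skeletal muscle list and 20 of 52 (38.5%) of the tendon and ligament list. So were 15 of 41 (36.6%) of the blood and macrophage list, 15 of 31 (48.4%) of the epidermal list and 8 of 20 (40.0%) of the nerve and Schwann cell list.

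Lists from the same element resembled each other more than lists from the same limb or the same digit. The mean Jaccard index, the number of shared regions divided by the number in either list, was 0.7174 for pairs of the same element and 0.6761 for pairs of different elements, a difference of 0.0413 (one-sided exact permutation p = 0.0312, the smallest that 32 labellings allow). The difference was 0.015 for limb (0.703 against 0.688, one-sided exact permutation p = 0.0312) and 0.0125 for digit (0.7039 against 0.6914, one-sided exact permutation p = 0.00463, the smallest that the labellings allow). Lists that differed only in element had a Jaccard index of 0.703 ± 0.024 (SD, 6 pairs), those that differed only in limb 0.727 ± 0.023 (6 pairs) and those that differed only in digit 0.728 ± 0.040 (12 pairs). When all lists were limited to their 36194 most significant peaks the digit difference was -0.0004, still the highest of all labellings (exact permutation p = 0.00463). Pairs of the same limb and element, which always differ in digit, lower it, and without them it was 0.0247, or 0.0148 at equal length (exact permutation p = 0.00463 for each). Without the metacarpal digit III list it was -0.0006 (exact permutation p = 0.0556).

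**Figure D1:**
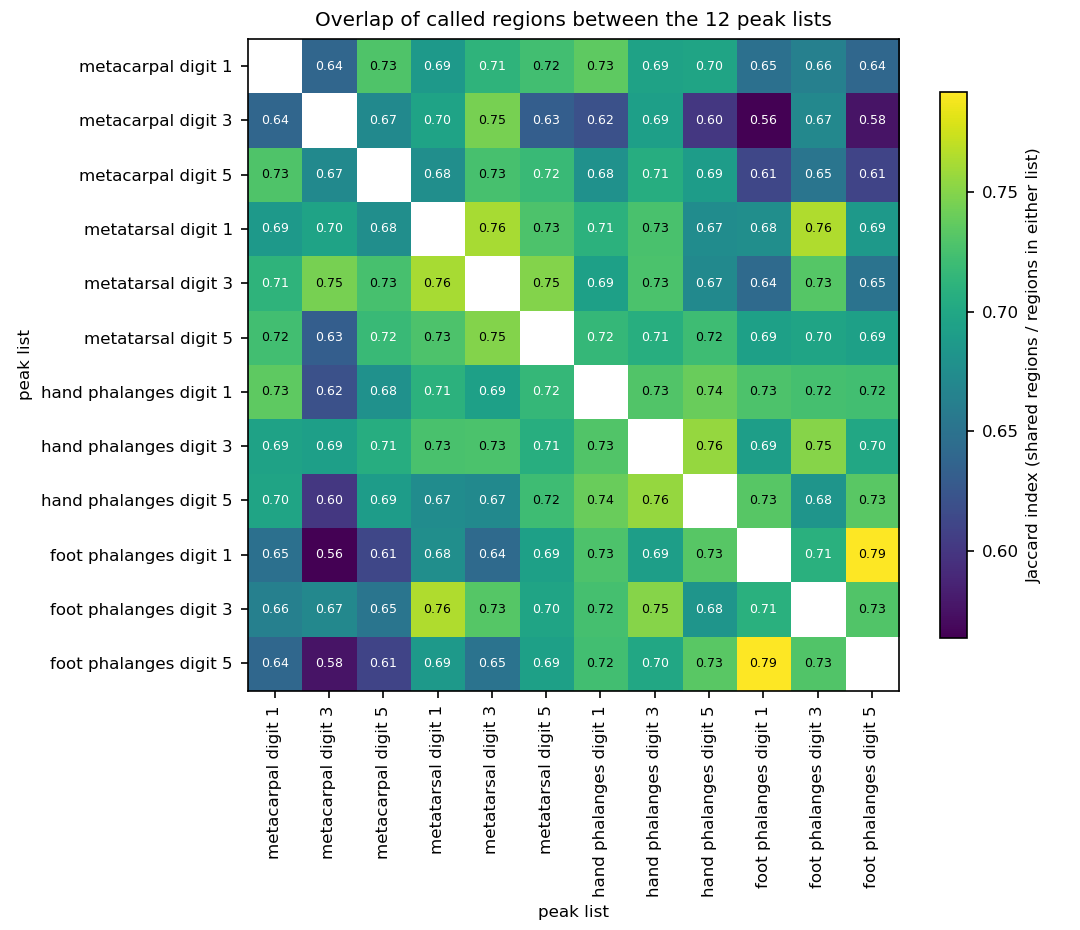
Jaccard index of called regions for each pair of the 12 peak lists, with lists on both axes ordered by element, limb and digit, and a colour scale without unit. Pairs of the same element average 0.7174 and pairs of different elements 0.6761.

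The first comparison asked which open chromatin separates the hindlimb from the forelimb. Hindlimb chondrocytes had 50 regions called in all 6 hindlimb lists and in no forelimb list, and forelimb chondrocytes had 4 of the reverse kind. A hindlimb region lay 9.9 kb from Tbx4 (chromosome 11, 85875237 to 85877779), the T-box transcription factor expressed in hindlimb but not forelimb buds, between Tbx2 and Tbx4. Another lay 11.6 kb from Nfatc1 (chromosome 18, 80593243 to 80596018), a calcineurin-dependent transcription factor. Pitx1, the homeobox gene that directs hindlimb identity, had 3 to 5 called regions in each hindlimb list and 1 to 3 in each forelimb list. The means were 4.33 ± 0.82 and 2.33 ± 0.82 (SD, n = 6 lists each, two-sided exact permutation p = 0.0312). Hoxc9 and Hoxc12 of the HoxC cluster, which patterns the hindlimb, went the same way, and no other listed HoxC gene passed. Hoxc9 had 2.5 ± 0.84 against 0.83 ± 0.41 regions and Hoxc12 had 1.83 ± 0.75 against 0.5 ± 0.55 (exact permutation p = 0.0312 for each, n = 6 lists).

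The fixed rule named further hindlimb regions. Adamts17, a secreted metalloprotease, had 2, on chromosome 7: 67167384 to 67169647, 15.3 kb beyond the gene, and 66932636 to 66937423, inside it. Atoh8, a basic helix-loop-helix transcription factor, had 1 at 13.1 kb (chromosome 6, 72247432 to 72250362). Others lay inside Adk (chromosome 14, 21286920 to 21288455), Arhgap10 (chromosome 8, 77419166 to 77422505), Atp2b2, a plasma membrane calcium pump (chromosome 6, 113852003 to 113853002), and Cacna1e, a voltage-gated calcium channel (chromosome 1, 154631622 to 154634107). Of the 4 forelimb regions, 1 lay 0.1 kb from an end of Mapkapk3, a kinase downstream of p38 (chromosome 9, 107253292 to 107256310). The others were assigned to Pou4f3 at 54.2 kb (chromosome 18, 42449282 to 42451383), to Slc39a11, a zinc transporter, at 112.2 kb (chromosome 11, 113131313 to 113134038), and to Galc at 736.3 kb (chromosome 12, 97465268 to 97466756). Of the 13 limb identity genes with a region, 3 had more called regions in hindlimb lists (Pitx1, Hoxc9 and Hoxc12), none had fewer and 10 did not pass. Among those 10, Tbx4 had 5.83 ± 0.98 regions in hindlimb and 4.17 ± 0.75 in forelimb lists (exact permutation p = 0.0625, n = 6 lists each). Merging hid a stretch inside Tbx4 (chromosome 11, 85887936 to 85892480), covered by peaks of all 6 hindlimb lists and of no forelimb list. Wide hindlimb peaks joined this stretch to peaks that forelimb lists share, so it did not count as a separating region. The stretch was picked after its values were seen. Hoxc11 had 1.67 ± 0.52 and 0.83 ± 0.75 (exact permutation p = 0.125), and Hoxc10 had 1.17 ± 0.41 and 1 in every forelimb list (exact permutation p = 1). Tbx5, the forelimb T-box gene, had 6 ± 2.45 and 6.83 ± 2.32 (exact permutation p = 0.594). In the joint list, Nfatc1 had more regions in hindlimb lists (10.17 ± 0.75 against 8.67 ± 1.37, exact permutation p = 0.0312). At equal list length none of these 4 genes passed: the differences were 1.67 for Pitx1, 1.0 for Hoxc9, 0.67 for Hoxc12 and 1.0 for Nfatc1 (exact permutation p = 0.0625, 0.0625, 0.25 and 0.188). Over all 186 list genes with a region, 4 were higher in hindlimb lists and none lower, against at most 5.8 expected at this threshold. Trps1, lower in hindlimb lists, did not pass here (16.5 ± 4.55 against 22 ± 5.37, exact permutation p = 0.0625) but did at equal list length (13.33 ± 4.32 against 19 ± 3.22, exact permutation p = 0.0312). No gene passed Benjamini-Hochberg adjustment (smallest adjusted exact p = 0.684).

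As a share of all called regions, regions assigned to the limb identity genes were more frequent in hindlimb lists, at 11.6 ± 2.01 per 10000 called regions against 9.16 ± 1.16 in forelimb lists (SD, n = 6 lists each, exact permutation p = 0.0312, adjusted p = 0.146 over 70 tests). Growth plate signalling genes, which encode BMP, TGF-beta, FGF, IGF and WNT pathway members, took 32.3 ± 1.66 against 29.68 ± 1.7 (exact permutation p = 0.0312, adjusted p = 0.146). Markers of other cell types moved with the limb as well. Skeletal muscle genes took 5.72 ± 0.83 against 4.23 ± 0.8 and endothelial genes 12.98 ± 0.57 against 12.08 ± 0.7 (exact permutation p = 0.0312 and adjusted p = 0.146 for each). Genes of resting and proliferating chondrocytes took 33.92 ± 2.39 in hindlimb and 36.96 ± 3.08 in forelimb lists (exact permutation p = 0.188), and posterior HoxA and HoxD genes 2.69 ± 0.37 and 2.63 ± 0.48 (exact permutation p = 0.719). The other 8 lists did not pass either, and no list passed the adjustment. Of these 4 differences, the endothelial one was kept in 2 of 6 alternatives (0.24 to 0.88), those of muscle and growth plate signalling genes in 4 of 6, and that of limb identity genes in 6 of 6. The growth plate difference no longer passed at equal list length (2.18, exact permutation p = 0.0625). These shares were added after the data were seen.

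**Figure D2:**
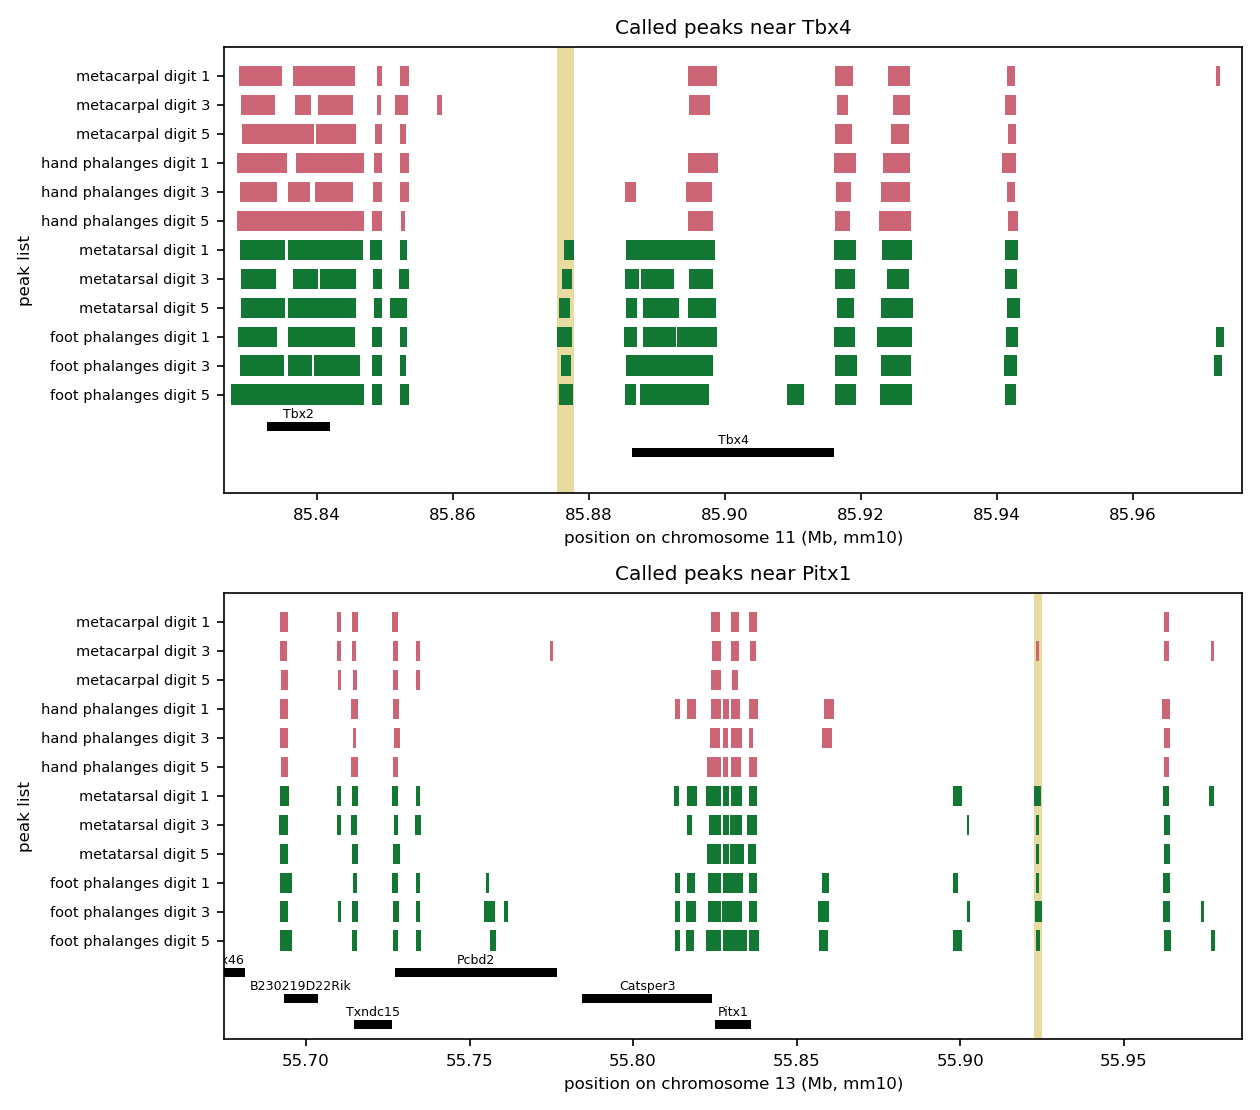
Called peaks of the 12 lists (rows; forelimb lists in red, hindlimb lists in green) near Tbx4 on chromosome 11 and Pitx1 on chromosome 13, with position in Mb on mm10 on the horizontal axis and protein-coding genes as black bars. The yellow band near Tbx4 (85875237 to 85877779) holds peaks in 6 of 6 hindlimb and 0 of 6 forelimb lists, and the band near Pitx1 (55922661 to 55924984) in 6 hindlimb lists and 1 forelimb list.

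Of the 32 splits of the lists within element and digit, the split by limb gave the most regions called only on the hindlimb side (50, exact permutation p = 0.0312). The 4 forelimb regions did not stand out (3 of 32 splits as large). Each other split was ranked by its larger direction, so this share of splits can be too high. Of the hindlimb regions, 24 lay inside genes, 26 between genes and none within 1 kb of a gene end (0.0%, Wilson 95% interval 0.0 to 7.1%), against 19.1% of the regions called in 2 or more lists (Fisher's exact test, adjusted p = 8.99e-05). Against regions called in just as many lists, the difference did not pass (Fisher's exact test, adjusted p = 0.463). No gene list was over-represented near the regions of either limb after adjustment (the limb identity list near hindlimb regions: 1 region, permutation test over genes, p = 0.0225, adjusted p = 1). At equal list length the counts were 36 and 10, each the highest of the 32 splits (4 for the highest other split, exact permutation p = 0.0312 for each). The forelimb count thus stood out at equal length, but not in the lists as deposited, with 50% cover, with the more significant 50% of peaks, with 500-bp windows or with the relaxed rule. The Tbx4 and Nfatc1 regions were then called in 4 of 6 hindlimb lists each and in no forelimb list.

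The second comparison asked which open chromatin separates the phalanges from the metapodials. There were 78 regions called in all 6 phalanx lists and in no metapodial list, and 60 of the reverse kind. Among the phalanx regions, 1 lay 33.4 kb from Msx1, a homeobox gene of the distal limb (chromosome 5, 37857006 to 37859038), 1 lay 35 kb from Tgfbr2, a TGF-beta receptor (chromosome 9, 116209625 to 116211100), and 1 lay inside Nfatc1 (chromosome 18, 80666492 to 80673233). Among the metapodial regions, 1 lay 117.3 kb from Fgf18, a growth factor of the growth plate (chromosome 11, 32998710 to 33000661). Alx4, a homeobox gene of the anterior limb, had 4.5 ± 0.84 called regions in phalanx lists and 1.67 ± 1.03 in metapodial lists (SD, n = 6 lists each, exact permutation p = 0.0312), whereas Acan and Col11a1, which encode cartilage matrix proteins, had fewer in the phalanges (5.33 ± 0.82 against 6.67 ± 1.03 and 4.5 ± 1.05 against 6.17 ± 0.98, exact permutation p = 0.0312 for each).

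Outside the gene lists, Dysf, a membrane repair protein of muscle, Grm4, a glutamate receptor, Klhl5 and Usp24, a deubiquitinase, each had 2 phalanx regions. Those nearest to a gene end were at 84166827 to 84169117 on chromosome 6 (inside Dysf) and 27503923 to 27507052 on chromosome 17 (inside Grm4). For the other 2 genes they were at 65168082 to 65170866 on chromosome 5 (centred 1.3 kb beyond Klhl5 and overlapping its end) and 106099777 to 106104830 on chromosome 4 (213.7 kb from Usp24). Ablim1 had 1 region inside the gene (chromosome 19, 57115883 to 57120383) and Arhgef28 had 1 at 246.9 kb (chromosome 13, 97650773 to 97652568). Metapodial regions lay inside Agr3 (chromosome 12, 35934100 to 35936079), Armc4 (chromosome 18, 7139205 to 7141218) and Atxn2 (chromosome 5, 121758511 to 121760163). Further ones lay between genes next to 1700012B07Rik (chromosome 11, 109851750 to 109854023), 2510009E07Rik (chromosome 16, 21718979 to 21720301) and A230072I06Rik (chromosome 8, 12297699 to 12299401). Of 25 genes of anterior-posterior digit patterning, Alx4 was higher in the phalanges and Bmp2 was lower (11.5 ± 2.51 against 16.17 ± 4.92 regions, exact permutation p = 0.0312). The other 23 did not pass, among them Msx1 (5.67 ± 0.82 against 3.83 ± 0.75, exact permutation p = 0.0625). Of 19 genes of resting and proliferating chondrocytes, 2 were lower (Acan and Col11a1) and 17 did not pass. Foxa2, of the 14 prehypertrophic and hypertrophic genes with a region, was lower (11.67 ± 3.39 against 14.33 ± 4.08, exact permutation p = 0.0312), and Tfap2a, of the 9 epidermal genes with a region, was higher (8.33 ± 0.52 against 6.17 ± 0.75, exact permutation p = 0.0312). At equal list length Acan, Bmp2 and Tfap2a passed again, and Alx4 (1.5), Col11a1 (-1.17) and Foxa2 (-2.17) did not (exact permutation p = 0.125, 0.0625 and 0.0625). With gene bodies and 10 kb flanks none of the 6 passed (Acan -0.83, exact permutation p = 0.25). None of these 2 higher and 4 lower genes passed adjustment (smallest adjusted exact p = 0.684).

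Regions of 4 lists took a larger share of the called regions in phalanx lists. Per 10000 called regions, anterior-posterior patterning genes took 44.54 ± 2.51 against 40.87 ± 1.85, genes of perichondrium and osteoblasts 22.92 ± 1.94 against 19.72 ± 1.68, limb identity genes 11.5 ± 2.08 against 9.26 ± 1.26 and skeletal muscle genes 5.57 ± 0.88 against 4.38 ± 1.02 (SD, n = 6 lists each, exact permutation p = 0.0312 and adjusted p = 0.146 for each). The patterning difference was kept in 3 of 6 alternatives (1.85 to 5.09), the muscle difference in 4 of 6 and the other 2 in 5 of 6. Perichondrial cells and muscle lie outside the cartilage. The other 10 lists did not pass, including resting and proliferating chondrocytes (34.57 ± 2.65 against 36.31 ± 3.45, exact permutation p = 0.219) and joint genes (27.54 ± 2.52 against 27.47 ± 1.81, exact permutation p = 0.906).

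**Figure D3:**
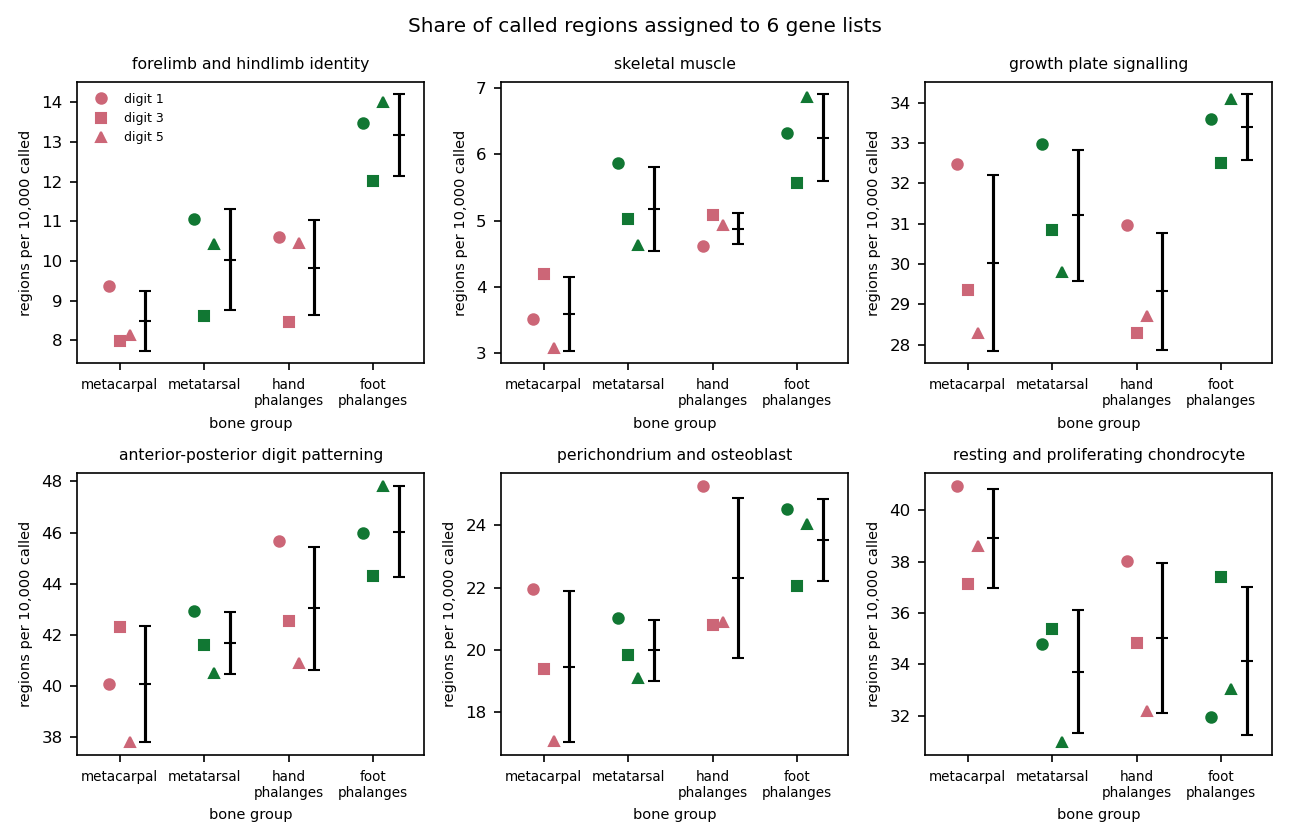
Regions assigned to 6 gene lists per 10000 called regions (vertical axes, which do not start at 0) in the metacarpal, metatarsal, hand phalanx and foot phalanx lists, with 1 point per peak list (circle, square and triangle for digits I, III and V; forelimb red, hindlimb green) and the mean ± SD of 3 lists in black. Limb identity regions average 11.6 in hindlimb and 9.16 in forelimb lists.

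The split by element gave more regions than any other of the 32 splits, both for the phalanges and for the metapodials (exact permutation p = 0.0312 for each). None of the 60 metapodial regions and 2 of the 78 phalanx regions (2.6%, Wilson 95% interval 0.7 to 8.9%) lay within 1 kb of a gene end, against 19.1% in the background (Fisher's exact test, adjusted p = 2.88e-05 and 6.54e-05). Neither share differed detectably from that of regions called in as many lists (Fisher's exact test, adjusted p = 0.463 and 1). No gene list passed the test of over-representation. At equal list length the metapodial count rose to 111. The regions near Msx1, Tgfbr2, Nfatc1 and Fgf18 were then called in 5 of the 6 lists of their class each, and with 50% cover in 4, 4, 4 and 5, so none of them separated its class under these 2 alternatives.

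**Figure D4:**
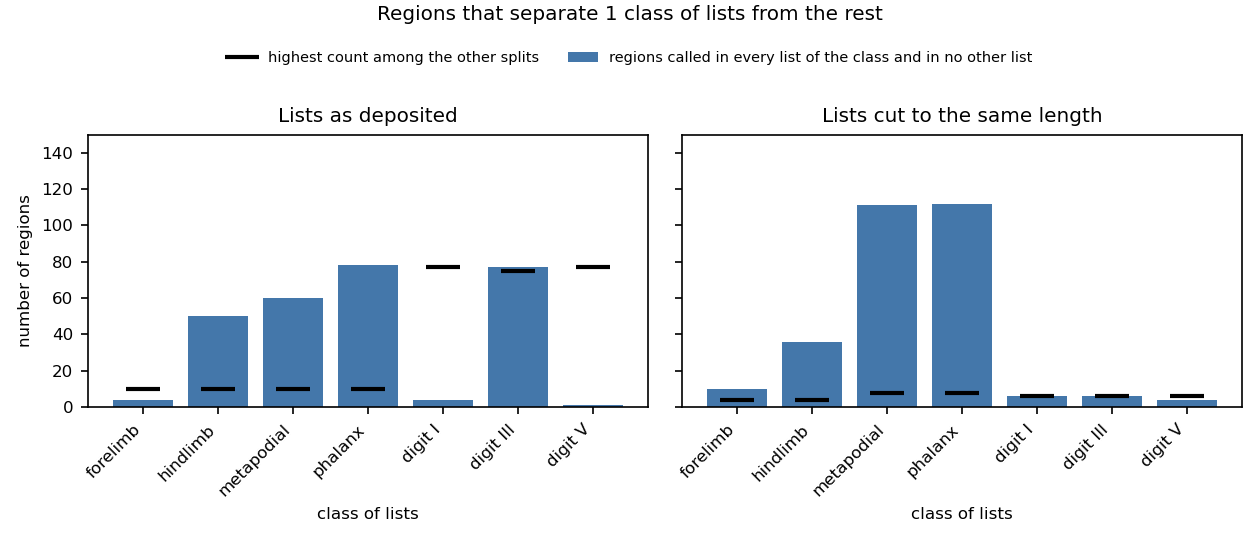
Number of regions called in every list of a class and in no other list (bars, vertical axis from 0) for the 7 classes of lists on the horizontal axis, with the highest count of any other split as a black line. The left panel uses the lists as deposited and the right panel the 36194 most significant peaks of each list, where the digit III count falls from 77 to 6.

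The third comparison asked whether single digits have open chromatin of their own. Digit III had 77 regions called in all 4 of its lists and in none of the other 8, digit I had 4 and digit V had 1. The digit I regions included 1 inside Runx1, a transcription factor of perichondrium and blood (chromosome 16, 92630107 to 92634623), and 1 at 63.5 kb from Smad2, a TGF-beta signal transducer (chromosome 18, 76373948 to 76376596). In digit I, Msx2, a homeobox gene of the limb bud, had 10.75 ± 1.26 called regions against 8.25 ± 1.67 in the other digits, and Tbx5 had 8.25 ± 1.89 against 5.5 ± 2 (SD, n = 4 and 8 lists, exact permutation p = 0.037 and 0.0494). At equal list length the digit III count was 6, no higher than the highest of the other splits. The Runx1 region was then called in 2 of 4 digit I lists and the Smad2 region in 3.

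Wnt4, a joint gene (6 ± 0.82 against 3.88 ± 0.99 regions, exact permutation p = 0.0247), and Sp7, an osteoblast transcription factor (4.75 ± 0.96 against 3.5 ± 0.93, exact permutation p = 0.0494), were also higher in digit I lists. The endothelial genes Cdh5 (9 ± 2.16 against 13.38 ± 2.39) and Emcn (1.5 ± 1 against 2.38 ± 0.52) were lower (exact permutation p = 0.037 for each). At equal length Wnt4 and Sp7 did not pass (exact permutation p = 0.0741 for each), and Msx2, Tbx5, Cdh5 and Emcn did. The other digit I regions lay inside Btbd9 (chromosome 17, 30238746 to 30243179) and Slc17a5, a lysosomal sialic acid transporter (chromosome 9, 78537991 to 78541042). At equal length these were called in 2 and 3 of 4 digit I lists, and 4 other lists had a peak within 1 kb of the Btbd9 region. In digit III, 22 list genes had more regions and none fewer. Among them were 8 of 19 resting and proliferating chondrocyte genes, with Trps1 at 23.5 ± 5 against 17.12 ± 4.7 and Col2a1 at 2.5 ± 0.58 against 1.75 ± 0.46 (exact permutation p = 0.0123 and 0.037). They also held 5 of 25 patterning genes, including Bmp2 (17.75 ± 5.44 against 11.88 ± 2.3, exact permutation p = 0.0123). These counts came from longer lists. At equal length Trps1 (2.75), Col2a1 (0.25) and Bmp2 (1.0) did not pass (exact permutation p = 0.111, 0.333 and 0.358), and Sox6, Barx2, Sall1 and Bmp7, also among these genes, changed sign (-1.25, -0.25, -0.12 and -0.12). The digit III regions named by the rule were assigned to Adam3, Angpt2, Apob, Abi3bp, Aebp2 and 4930519L02Rik. Digit V, whose lists were shorter on average (37919 against 43759.5 peaks, exact permutation p = 0.148), had 11 list genes with fewer regions and none with more. Runx1 was at 13.75 ± 3.77 against 20.12 ± 2.85 and Creb5, a regulator of articular cartilage, at 13.5 ± 4.04 against 21.12 ± 3.14 (exact permutation p = 0.0123 for each). At equal list length these differences were -2.5 and -4.38 and did not pass (exact permutation p = 0.247 and 0.136). Its single region lay 226.3 kb from Hrh4 (chromosome 18, 13248763 to 13251189). Of the 186 list genes with a region, up to 9.2 were expected by chance at this threshold in each digit comparison. The numbers found were 6 for digit I, 22 for digit III and 11 for digit V. No gene passed adjustment in any digit comparison (smallest adjusted exact p = 0.286, for digit III).

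As shares of called regions per 10000, digit I lists held more regions of joint genes (29.42 ± 1.17 against 26.54 ± 1.76, exact permutation p = 0.037, adjusted p = 0.162) and of perichondrium and osteoblast genes (23.18 ± 2.03 against 20.39 ± 2.09, exact permutation p = 0.0123, adjusted p = 0.146). The same held for shares of growth plate signalling genes (32.51 ± 1.12 against 30.23 ± 2.11, exact permutation p = 0.0247, adjusted p = 0.146) and of blood and macrophage genes (7.04 ± 0.41 against 6.26 ± 0.6, exact permutation p = 0.0123, adjusted p = 0.146; n = 4 and 8 lists throughout). In digit III lists the shares were smaller for limb identity genes (9.27 ± 1.85 against 10.94 ± 1.96, exact permutation p = 0.0123) and for posterior HoxA and HoxD genes (2.25 ± 0.29 against 2.86 ± 0.29, exact permutation p = 0.0123). Digit III lists are longer, so their shares are divided by more called regions, and a smaller share need not mean fewer regions. Their share of epidermal genes was smaller too (5.24 ± 0.46 against 5.89 ± 0.43, exact permutation p = 0.0247), and that of prehypertrophic and hypertrophic genes was larger (16.08 ± 0.34 against 15.32 ± 0.7, exact permutation p = 0.0494). Digit V lists held a larger share of regions of endothelial genes (13.02 ± 0.7 against 12.28 ± 0.71, exact permutation p = 0.0123). No share passed adjustment. Digit I lists also had a higher median fold enrichment (12.23 ± 2.5 against 9.93 ± 0.74, exact permutation p = 0.037). In digit I the blood difference was kept in 2 of 6 alternatives (0.36 to 0.8) and was lost at equal list length, the joint difference in 4 of 6 and the other 2 in 5 of 6. In digit III the epidermal difference was kept in 2 of 6 and changed sign at equal list length (0.11), that of prehypertrophic genes was kept in 3 of 6, of posterior HoxA and HoxD genes in 4 of 6 and of limb identity genes in 5 of 6. The endothelial difference in digit V was kept in 2 of 6 (-0.22 to 0.77).

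Among the 81 splits that take 1 list per bone group, the digit III split gave the most regions (exact permutation p = 0.0123), although its lists are longer and another split gave 75, and digits I and V did not stand out (exact permutation p = 0.185 and 0.617). Of the digit III regions, 5 (6.5%, Wilson 95% interval 2.8 to 14.3%) lay at a gene end (Fisher's exact test, adjusted p = 0.00572). The difference turned to 3.0 percentage points above a background of regions called in 4 lists (Fisher's exact test, adjusted p = 0.463).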

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

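The tests of explanations and the counts over other splits in this part were chosen after the results were seen.

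A search for lists that stand apart from the rest of their class covered 140 groups of lists (20 measures in 7 classes) and found 7, as many as the 7 that chance gives at about 1 in 20. Metacarpal digit I had a median fold enrichment of 15.62, the next metapodial list being at 10.94. Metacarpal digit III had 1271 peaks on the X chromosome, the next metapodial list having 986, and metatarsal digit I had 980, the next digit I list having 852. The share of endothelial regions in hand phalanges digit I was 10.87 per 10000 called regions, the nearest digit I list being at 12.39. The share of limb identity regions in foot phalanges digit III was 12.02, the nearest digit III list being at 8.61. The share of nerve and Schwann cell regions was 4.35 in hand phalanges digit V, against 3.53 in the nearest forelimb list, and 3.12 in foot phalanges digit III, against 3.35 in the nearest digit III list. Of 40 differences compared between groups of lists, 1 had the same sign for all 3 digits in a group and the opposite sign for all 3 in the other. Differences whose means alone went opposite ways were not counted, and the number that chance would give was not computed. Regions of tendon and ligament genes took a larger share in phalanges than in metapodials for all 3 digits of the forelimb (mean difference 0.87, from 0.73 to 1.03) and a smaller share for all 3 digits of the hindlimb (mean difference -0.15, from -0.22 to -0.1). That difference between limbs was not tested.

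The excess of digit III regions (77, with 75 for the highest other split and 1 of 81 splits as large) follows what longer lists would give. With every list limited to the same length the count was 6, and another split also gave 6. List length is therefore a candidate explanation for the excess. A difference in digit III chromatin cannot be told apart from list length here, since the 6 regions left at equal length did not exceed the other splits (6), although 4 of 81 splits gave as many and, with the relaxed rule as well, 3 of 81 (246, highest other 314).

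The larger number of hindlimb regions than forelimb regions was not fully accounted for by list length. At equal length the difference between the counts was 26 (36 against 10), smaller than the 46 in the lists as deposited. The highest difference of any other split at equal length was 4. Cells of other types could add hindlimb regions: 3 of 6 marker lists of other cell types had a higher mean share in hindlimb lists, 2 of them (skeletal muscle, and endothelium, which kept its call in 2 of 6 alternatives) at an exact p of 0.05 or under. None was lower at that threshold, though at equal length epidermis was (-0.13), which leaves this open. None of the hindlimb regions was assigned to a gene of these 6 lists, where at most 0.0595 per list were expected by chance. A hindlimb region lay 5994 bp from Vwf, an endothelial gene outside the lists that was picked after its value was seen. A difference between fore- and hindlimb chondrocytes, which the design names, stays open and was not tested separately.

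The regions that separate metapodials and phalanges were not accounted for by list length either, since at equal length the smaller count was 111 and the highest of the other splits was 8. Cells of other types might contribute to the phalanx regions: 4 of 6 marker lists of other cell types had a higher mean share in phalanx lists, 1 of them (skeletal muscle) at an exact p of 0.05 or under and none lower at that threshold. The perichondrium and osteoblast list, not among the 6, was higher in phalanx lists too (22.92 against 19.72, exact permutation p = 0.0312). None of the phalanx regions was assigned to a gene of the 6 lists, where at most 0.16 per list were expected by chance. Dysf, a muscle gene outside the lists, had 2 of the phalanx regions. A biological difference between the elements, which the design names, was not tested and stays open.

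No other split gave as many regions as the hindlimb (50 regions, highest other split 10, 1 of 32 splits as large), metapodial (60, highest other 10, 1 of 32) or phalanx class (78, highest other 10, 1 of 32). Each of these shares is the smallest that 32 splits allow, and none was adjusted over the 7 classes. Chance in the assignment of lists to classes is thus unlikely for these counts, but not excluded. For digit III (77, highest other 75, 1 of 81) the split also parts longer from shorter lists, so nothing beyond list length is read from it. In the lists as deposited other splits gave as many or more for the forelimb (4, highest other 10, 3 of 32), digit I (4, highest other 77, 15 of 81) and digit V regions (1, highest other 77, 50 of 81), so chance cannot be excluded. For digits I and V the highest other split was the split by digit III, whose lists are longer. Their shares of splits therefore do not measure chance alone. At equal length the forelimb count was 10 (highest other 4, 1 of 32), and 224 with the relaxed rule as well (highest other 206, 1 of 32). It was 0 with 50% cover and with the more significant 50% of peaks (32 of 32 each), 5 with 500-bp windows (4 of 32) and 136 with the relaxed rule (12 of 32). Whether the forelimb count stands out thus depends on the setting. Each other split was ranked by its larger direction, so the shares of splits given for the forelimb can be too high. The digit I count was 6 at equal length (highest other 6, 4 of 81), 314 with the relaxed rule as well (highest other 265, 1 of 81), 5 with 50% cover (24 of 81), 0 with the more significant 50% of peaks (81 of 81), 2 with 500-bp windows (45 of 81) and 191 with the relaxed rule alone (25 of 81). For the number of gene lists whose share differed, no other split gave as many as limb (4, highest other 1, 1 of 32). The count was 2 with the more significant 50% of peaks. No share passed adjustment (smallest adjusted exact permutation p = 0.146) and the shares were added after the data were seen, so chance is not taken as excluded. For element (4, highest other 3, 1 of 32) the margin was 1 list and the count was 3 on autosomes, 3 with 500-bp windows and 1 with the more significant 50% of peaks, so chance is not taken as excluded. For digit I and digit III (4 each, highest other 6, 3 of 81 each) other splits gave more, so chance is not taken as excluded, nor is it for digit V (1, highest other 6, 35 of 81). For the number of list genes whose called regions differed, 1 of 32 splits was as large for element (6, highest other 4), but up to 5.8 genes were expected, so chance is not taken as excluded. Nor is it for digit III (22, highest other 26, 4 of 81), whose lists are longer, and it cannot be excluded for limb (4, highest other 9, 4 of 32), digit I (6, highest other 26, 14 of 81) or digit V (11, highest other 26, 9 of 81).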

How the results depend on the processing

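The alternatives named here were planned, except equal length combined with the relaxed rule, leaving out pairs of the same stratum, the background of regions called in as many lists, and all alternatives of the gene list shares and of the regions per gene, which were chosen after seeing the data. No paired analysis was possible because each peak list pools the 3 libraries of its group, so the replicate numbers that the labels share across groups are in no measured value. The motif test and its 4 alternatives were not run, since no genome sequence was used here. Depth per library is unknown, so a region missing from a list can lie below its threshold.

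The similarity by limb and by element kept its sign and an exact p of 0.0312 under every setting except leaving out lists. Without 1 list it ranged from 0.0087 to 0.021 for limb and from 0.031 to 0.0489 for element, and the p rose to 0.0625 for limb without metacarpal digit V (0.0122), metatarsal digit V (0.0161) or foot phalanges digit I (0.0101), and for element without foot phalanges digit I (0.0313; the cause was not tested). The similarity by digit was -0.0004 at equal length, still the highest of all labellings (exact p = 0.00463). Pairs of the same limb and element, which always differ in digit, lower this difference by construction. Without them it was 0.0247, and 0.0148 at equal length (exact p = 0.00463), but why equal length lowered both was not tested. It ranged from -0.0006 (without metacarpal digit III, exact p = 0.0556; the cause was not tested) to 0.0197 without 1 list.

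Counts of separating regions are given in the order forelimb, hindlimb, metapodial, phalanx, digit I, digit III and digit V (4, 50, 60, 78, 4, 77 and 1). With the more significant 50% of each list they were 0, 15, 23, 13, 0, 48 and 0. At equal length they were 10, 36, 111, 112, 6, 6 and 4, with 1 of 32 splits as large for the forelimb and 4 of 81 for digit I and for digit III. Of these, forelimb, metapodial, digit III and digit V moved by over 1.5 times. With the rule relaxed by 1 list they were 136, 564, 760, 691, 191, 1492 and 34, since the rule admits more regions, and with equal length as well 224, 344, 808, 825, 314, 246 and 169. The forelimb count was 0 where peaks had to cover 50% of a region. The digit I and digit V counts were 2 each with 500-bp windows. Apart from the relaxed rule, the cause was not tested. Leaving out 1 list gave 4 to 13, 53 to 113, 60 to 149, 81 to 194, 4 to 23, 82 to 2.2e+02 and 1 to 3, higher by construction. The hindlimb count was 94 without metacarpal digit III, 79 without hand phalanges digit I, 113 without metatarsal digit III and 86 without metatarsal digit V. The metapodial count was 149, 94, 106, 133 and 121 without metacarpal digit I, metacarpal digit V, hand phalanges digit III, metatarsal digit V and foot phalanges digit III, and the phalanx count 194, 122 and 130 without metatarsal digit I, hand phalanges digit I and hand phalanges digit V. The digit III count was 139, 176, 186 and 204 without metacarpal digit V, metatarsal digit I, metatarsal digit III and foot phalanges digit III, and highest without hand phalanges digit III. The forelimb count was 8, 9, 13, 8, 11 and 10 without metacarpal digit I, hand phalanges digit I, hand phalanges digit V, metatarsal digit I, metatarsal digit III and foot phalanges digit III. The digit I count was 22, 9, 23, 14 and 9 without metacarpal digit I, hand phalanges digit I, metatarsal digit I, foot phalanges digit I and foot phalanges digit III. Without hand phalanges digit III the digit V count was 2, and without the digit V list of metacarpals, metatarsals or foot phalanges it was 3.

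No pair of gene list and set passed adjustment for the values in the report (2 had an unadjusted p under 0.05), but 3 pairs did in alternatives (permutation test over genes, adjusted p = 0.0098 each). These were the perichondrium list in digit I within 100 kb and with gene bodies, and the prehypertrophic list in the forelimb at equal length. Each rested on 1 region, with an expected number of 0 among the matched genes, so that a single region reached the smallest p the draws can give (0.0001). The number of gene lists whose share differed fell with the more significant 50% of peaks to 2 for limb and to 1 each for element, digit I and digit III. It fell with 500-bp windows to 2 for digit III, and for digit V to 0 with 50% cover, at equal length and with 500-bp windows; the cause was not tested. Of the differences in share that passed unadjusted, that of limb identity regions by limb alone kept its side of the threshold in 6 of 6 alternatives (2.18 to 3.84). The others were kept in 2 to 5 of 6. Differences that changed sign were joint genes in digit I (-0.33, more significant 50%), epidermal genes in digit III (0.25, more significant 50%, and 0.11, equal length) and endothelial genes in digit V (-0.22, 50% cover). Of differences in regions per gene, 36 weakened at equal length, 37 with gene bodies and 14 with 500-bp windows. Those kept (59, 61 and 85) include ones that never passed and overstate what held. At equal length the digit III differences turned to -0.25 for Barx2, -0.12 for Bmp7, -0.12 for Sall1 and -1.25 for Sox6; the cause was not tested. Against regions called in as many lists, the digit III share at gene ends was reversed (3.0 percentage points). Of the 39 named regions, 10 separated their class at equal length, 16 with 50% cover, 37 with the 1 kb margin and none with the more significant 50% of peaks.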

Other observations

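The regions described first in this part were chosen after their values were seen, and so were the counts over all genes. With 500-bp windows round the summits, which split wide merged regions, Tbx5 gained a window called in all 6 forelimb lists and in no hindlimb list (chromosome 5, 119800338 to 119800898). It lies inside Tbx5, 4.1 kb from an end of the gene, within a merged region that was called in all 6 forelimb and in 3 hindlimb lists. With these windows 5 regions were called in the forelimb lists alone. With each other split taken in its larger direction, 4 of the 32 splits gave as many (highest other 13), so chance cannot be excluded. Fzd2, a WNT receptor, gained a window called in the 6 metapodial lists alone (chromosome 11, 102632678 to 102633228, 24.9 kb from the gene), within a merged region that was called in 6 metapodial and 2 phalanx lists. Next to the HoxD cluster, 3 regions beyond Mtx2 separated the limbs with 1 list allowed to differ on each side: 74925913 to 74927301 (5 hindlimb lists and 1 forelimb list), 75010788 to 75013387 (5 and 0) and 75101248 to 75102406 (6 and 1) on chromosome 2. A region 87.6 kb from Pitx1 (chromosome 13, 55922661 to 55924984) was called in 6 hindlimb lists and in metacarpal digit III.

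Over 9877 genes whose number of regions varied between lists of equal length, hindlimb lists had more regions near Mgmt (15.83 ± 1.72 against 11.33 ± 2.5, SD, n = 6 lists each), Cadm1, a cell adhesion molecule (7.17 ± 1.47 against 3.17 ± 2.04), and Adamts17 (9.5 ± 0.55 against 6.33 ± 1.03). They had fewer near Trps1, a repressor of chondrocyte maturation (13.33 ± 4.32 against 19 ± 3.22), and Gpc6, a glypican needed for skeletal growth (13.5 ± 2.81 against 18.67 ± 2.42; exact permutation p = 0.0312 for each). Phalanx lists had more regions near Zfp536 (14.67 ± 0.52 against 10 ± 1.1) and Pax2 (10.33 ± 0.82 against 5.67 ± 2.66), and fewer near Trps1 (13.33 ± 4.08 against 19 ± 3.52), Gpc5 (11 ± 2.53 against 18.67 ± 3.56) and Pde4d (28.17 ± 4.54 against 35.83 ± 5.34; exact permutation p = 0.0312 for each). In the lists as deposited Trps1 did not pass for limb or for element (exact permutation p = 0.0625 for each). Digit I lists had more near Runx1 (17.75 ± 1.26 against 12.38 ± 1.41, n = 4 and 8 lists, exact permutation p = 0.0123) and Gas1, a hedgehog co-receptor (19.75 ± 2.22 against 14.5 ± 2.39, exact permutation p = 0.0123), and fewer near Cep128 (1.25 ± 0.5 against 5.5 ± 3.02, exact permutation p = 0.0123). In the lists as deposited Runx1 did not pass for digit I (21.5 ± 2.52 against 16.25 ± 4.06, exact permutation p = 0.0988). No gene passed adjustment (smallest adjusted exact p = 0.602, for element).

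The number of genes past an exact p of 0.05 at equal length was 124 for limb (82 higher and 42 lower in hindlimb lists, highest other split 39, 1 of 32 splits as large) and 374 for element (162 higher and 212 lower in phalanx lists, highest other 73, 1 of 32). It was 373 for digit I (highest other 322, 1 of 81) and 322 for digit III (highest other 373, 2 of 81). For limb, element and digit I no other split gave as many. Since no gene passed adjustment and this count was chosen after the results were seen, chance is still not taken as excluded there. Nor is it taken as excluded for digit III, where another split gave more. Digit I lists also differed in median fold enrichment (12.23 against 9.93, exact permutation p = 0.037) and in the lowest −log10 p-value kept (42.65 against 31.8, exact permutation p = 0.037). Lists of equal length are not matched for these, so the digit I count is not set apart from a difference in peak quality. The highest other split was the split by digit III for digit I, and by digit I for digit III. For digit V the number was 151 (highest other 373, 14 of 81), and chance cannot be excluded.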
